A study of Oryza sativa with 8 samples.

How the data were processed

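RNA sequencing of 8 rice samples was analysed, 2 each of leaf blade control, leaf blade salt, leaf sheath control and leaf sheath salt, with groups taken from the sample titles and characteristics. Per the labels' protocols, libraries were made from total RNA of leaves with an mRNA kit after DNase digestion. Per the submitters' processing notes, HISAT was used, with no version or role given, and the genome build was mm10. That is a mouse build, so it cannot be the build of these rice identifiers, and the build, annotation, counting tool and test are not given in the sources used here.

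The authors deposited 2 tables, one per tissue, which hold genes already selected as changed and group values only. Per the file headers, the blade table gives a log2 fold change, the mean TPM, mean read count and mean FPKM of each group and a q-value. The blade read counts are estimated counts averaged over a group by the authors: 5.58% of genes had means that are not means of 2 whole numbers. Columns named Case1 were taken as salt, the one other blade group. Per the file headers, the sheath table gives a log2 fold change, an expression level of unnamed unit for each group, the mean of both levels, a standard error, a test statistic, a p-value and an adjusted p-value. The statistic behaves like a score from a Wald test in the deposited values, since the listed p equals its two-sided normal p within rounding. The deposited sheath log2 fold change was under 0.8 of statistic times standard error for 241 genes. For each named sheath gene it equals, within rounding, the log2 ratio of the 2 group levels with 1 added to each. It is thus a ratio of levels and not the estimate that was tested. The 2 tables differ in columns, fold estimate and threshold, so levels were compared within a table only. The highest deposited blade q-value was 0.0499 and the highest sheath p-value 2.8e-04, and no fold minimum was seen: the smallest absolute deposited log2 fold change was 0.165 in blades and 0.456 in sheaths. The sheath table held 3 identifiers of another form than the rest, which were kept in counts and not named. A median listed blade fold change lay 0.19 below the TPM ratio and 0.13 below the read ratio on the log2 scale, as a rescaling between libraries would give. By the ratio of mean TPM, 2400 listed blade genes were higher and 2223 lower.

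The design written before the data were examined foresaw tables of selected genes. No new test across all genes was made, and the authors' deposited fold changes and p-values are reported. The design also fixed the counts per direction and the list test, while Fisher's exact tests and the counting intervals were added after the tables had been looked at. Computed here were the counts per direction, the exact binomial test (two-sided) of each gene list's higher and lower members against the split of all listed genes of that tissue, Fisher's exact test of directions across shared genes, Benjamini-Hochberg adjustment over the 22 list tests and over the 10 list comparisons between tissues, and exact (Clopper-Pearson) 95% counting intervals of blade read ratios, scaled by the median offset from the read ratio. Intervals and floors cover counting error only. For a blade gene with 0 reads in a group, the fold was set against a floor of 3 reads over the group of 2 libraries. A count adjusted over the list alone could not be had, because unlisted members have no p. The tests were tried on simulated data: of random lists of 10 genes, 2.25% passed the binomial test in blades and 2.85% in sheaths, and of lists with each member higher at a chance of 95%, 92.2% and 91.6% passed. These rates hold for 10 listed members and p under 0.05 without adjustment. Most lists had fewer listed members, at most 6 in sheaths, and were judged after adjustment, so the rates do not apply to them. A short list can have all its members on the same side and still not pass. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

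The files do not pair identifiers with names, and the reference name table, of another assembly, held 0 of the 5827 listed identifiers. The 13 gene lists held 107 pairs of name and identifier fixed from general knowledge before the data were examined. For 84 of them the name table had the same name on the chromosome that the identifier states, 5 of these through another name of the gene that was added later. For 2 the name was on another chromosome, for 1 it occurred more than once, and for 20 it was not in the table. Locus number and table position ran in the same order in 346 of 347 pairs of such genes on a chromosome, and JAZ10 and JAZ11, which made the exception, were not named. All fixed members enter the list counts, and only genes that passed these checks are named. No coordinates are given. The 25 keyword lists could not be applied, since no descriptions of the genes were at hand. Genes were named by a rule fixed before the data were examined, applied to genes with a checked name: up to 10 largest rises and falls per tissue with a mean of at least 10 reads or a level of 1 in the higher group, up to 4 listed members per gene list, listed ion transport genes, and 5 shared genes per kind of direction. Up to 2 identifiers per direction, those with the most extreme fold changes of a table, were added after their values were seen. So were identifiers of some list members without a checked name that changed more than the named members of their list. The parts of the rule that need values per sample or a test between tissues could not be applied. Alternatives were a stricter threshold, a fold minimum, a filter on low values, other scales of the fold change and only members with a checked name.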

Results

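RNA was sequenced from leaf blades and leaf sheaths of rice (Oryza sativa) that was grown hydroponically and either kept as a control or exposed to 100 mM NaCl for 24 h. The 8 samples formed 4 groups of 2: blade control, blade salt, sheath control and sheath salt. The series addresses which transcripts change in a Japanese landrace that tolerates sodium within its tissues, set against a tolerant and a sensitive variety in physiology. The sample labels name no variety, and nothing in them says that the 2 samples of a group came from separate plants, so p-values then measure only the spread between these samples, which may be technical. The data analysed here were 2 lists of changed genes, one per tissue, with a mean per group and no value per sample. The blade list held 4623 genes with q up to 0.05 (highest 0.0499) and the sheath list held 1998 genes with adjusted p up to 0.004. A gene outside a list was not analysed here, and the lengths of the lists cannot be set against each other because they stop at different thresholds. The listed blade genes added up to a mean of 10745825 reads in control and 9995664 in salt samples, or 65.4% and 60.9% of all TPM, whereas the depth of the sheath libraries is unknown.

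In leaf blades with salt, 13 of the 16 abscisic acid genes were listed, all 13 of them higher, a split that passed its test but not with a log2 fold change of at least 1 required. LEA3-1 and the dehydrin gene RAB21 had the largest listed fold changes of the named genes that rose, and the catalase gene CATA had the largest fall of the named genes. Only 54 of the 5827 identifiers listed in either tissue had a checked name, all from the fixed lists. Ranks among named genes therefore do not rank the whole response. Of the 4623 genes in the authors' deposited table, 2392 were higher and 2231 lower with salt. The rises were larger: by the authors' deposited table, 917 genes rose and 578 fell by at least 1 on the log2 scale, and 393 rose and 120 fell by at least 2. These counts were the same with the genes at 0 reads in a group set to a floor of 3 reads over the group. The median log2 fold change in the authors' deposited table was 0.76 among genes that rose and -0.65 among those that fell.

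The late embryogenesis abundant (LEA) proteins and dehydrins, which protect cells during water loss, held the largest listed fold changes among the named genes. Of the 10 list members, 7 were in the authors' deposited table for blades and 7 of 7 were higher, with a median log2 fold change of 6.02, or 4.58 with the 1 member at 0 control reads set to the floor. LEA3-1 (Os05g0542500) went from 0.110 to 134 TPM, a log2 fold change of 10.11 with q = 3.5e-31 in the authors' deposited table. That control mean rests on 3 reads over both libraries, and the 95% counting interval of the 1107-fold ratio ran from 379-fold to 5383-fold. The authors' deposited table gave RAB21 (Os11g0454300), a dehydrin also called RAB16A, a rise from 0.230 to 144 TPM and a log2 fold change of 9.13. Its control libraries held 4 reads together, which gives a counting interval of 219-fold to 2059-fold. RAB16B rose by 6.02 and RAB16C by 3.67 on the log2 scale in the authors' deposited table. RAB16D had 0 control reads and a mean of 30 reads with salt, so against the floor it was at least 18.3-fold higher, while its 95% counting interval started at 14.4-fold. Against the 51.7% of all listed blade genes that were higher, the LEA and dehydrin split did not pass the exact binomial test once adjusted (two-sided p = 0.016, adjusted p = 0.12 over 22 list tests). No split of 7 members could lie further toward higher, so the result is not evidence against a direction.

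The abscisic acid list, which covers synthesis and breakdown of the hormone, the protein phosphatases 2C that restrain its signal and the bZIP factors that act downstream, was the one list whose direction passed. All 13 of its listed members were higher in the authors' deposited table, out of 16 members (two-sided exact binomial test, p = 2.7e-04, adjusted p = 0.0059), with a median log2 fold change of 1.25. The test treats genes as independent, which they are not, and several of these members are protein phosphatases 2C. Its p may therefore be too small. The largest listed change was that of Os07g0154100, a member without a checked name, at 7.32 on the log2 scale with q = 9.0e-21. Of the members with a checked name, PP2C68 rose most. It went from 1.12 to 16.9 TPM, a log2 fold change of 3.73 with q = 5.6e-40 in the authors' deposited table. The authors' deposited table gave log2 fold changes of 3.48 for PP2C51, 2.33 for PP2C49 and 2.04 for PP2C30. PP2C51 was low, at a mean of 4 reads in control samples and 49 with salt. When a log2 fold change of at least 1 was also required, 8 of 8 members were still higher, but the split no longer passed (exact binomial test, adjusted p = 0.46).

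Of 10 stress transcription factors, 5 were higher and 1 lower in the authors' deposited table for blades, and the split did not pass (exact binomial test, adjusted p = 0.44). The largest listed change, 3.77 on the log2 scale with q = 0.0058, was that of Os11g0126900, a member without a checked name. NAC6 rose from 79.9 to 212 TPM, HSFA2C, a heat stress factor, from 8.28 to 22.6 TPM, and NAC5 from 22.3 to 55.4 TPM, with log2 fold changes of 1.22, 1.23 and 1.10 in the authors' deposited table. SGR, the STAY-GREEN gene that acts in chlorophyll breakdown, rose from 1.43 to 18.0 TPM, a log2 fold change of 3.48 with q = 2.7e-35 in the authors' deposited table. Both listed members of the 3 senescence genes were higher (exact binomial test, adjusted p = 0.69). The lectin gene SALT, used as a salt marker, rose by 1.56 on the log2 scale from 2.15 to 7.24 TPM in the authors' deposited table, with q = 0.0068.

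Of 6 photosynthesis genes, 5 were in the authors' deposited table for blades, all 5 of them lower, and the split did not pass (exact binomial test, p = 0.026, adjusted p = 0.14). RBCS (Os12g0274700), a small subunit of Rubisco, went from 53569 to 28778 TPM, a log2 fold change of -1.09 with q = 6.6e-72 in the authors' deposited table. CAB2R, a light-harvesting chlorophyll protein, changed by -0.55 on the log2 scale and RCA, Rubisco activase, by -0.21 in the authors' deposited table. The mean reads of RBCS and CAB2R were not means of 2 whole numbers, so their counts were estimated and these values are less certain where similar copies share reads. RCA changed by only -0.02 as a ratio of mean TPM, because a listed fold change of a blade gene lay a median of 0.19 below its TPM ratio on the log2 scale.

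All 10 antioxidant enzymes of the list were in the authors' deposited table for blades, 7 higher and 3 lower (exact binomial test, adjusted p = 0.59). The catalase gene CATA fell from 375 to 98.4 TPM, a log2 fold change of -2.11 with q = 6.3e-147 in the authors' deposited table. The ascorbate peroxidase genes APX8 and APX7 had log2 fold changes of -0.56 and -0.29 in the authors' deposited table, while APX2 rose by 0.53 and the superoxide dismutase gene SODA by 0.44. Of the 13 aquaporins, which conduct water through membranes, 4 were higher and 3 lower in the authors' deposited table (exact binomial test, adjusted p = 1). TIP2;2, an aquaporin of the vacuolar membrane, fell from 435 to 245 TPM, a log2 fold change of -1.02 in the authors' deposited table. PIP1;3 rose by 0.53 and PIP2;1 by 0.43, and PIP2;7 changed by -0.38 and PIP2;2 by -0.26 on the log2 scale in the authors' deposited table. As ratios of mean TPM in the authors' deposited table, the changes were -0.18 for PIP2;7, -0.08 for PIP2;2 and -0.11 for APX7. The counts of PIP2;1 were estimated in the same way.

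Of 18 ion transport genes, 6 were higher and 1 was lower in the authors' deposited table for blades (exact binomial test, adjusted p = 0.32). The potassium transporter genes HAK1 and HAK7 rose by 1.61 and 1.31 on the log2 scale, HAK1 from 1.10 to 3.87 TPM and HAK7 from 9.46 to 26.8 TPM, in the authors' deposited table. HKT1;1, HKT1;4, HKT1;5 and HKT2;1, sodium transporters, and HAK5, HAK10 and CIPK24 were in neither list and were not analysed here. The compatible solute list, which covers proline and trehalose metabolism, had 2 members higher and 2 lower in the authors' deposited table (exact binomial test, adjusted p = 1). P5CS2 and P5CS1, which start proline synthesis, rose by 1.16 and 0.56, and TPP1, a trehalose phosphatase, changed by -0.98 on the log2 scale in the authors' deposited table. All 3 listed members of the 10 jasmonate genes were higher (exact binomial test, adjusted p = 0.46), among them the repressor genes JAZ12 and JAZ6 with log2 fold changes of 1.67 and 0.59 in the authors' deposited table. The 2 listed members of the 3 reference genes were also higher (exact binomial test, adjusted p = 0.69), and the actin gene ACT1 had a log2 fold change of 0.38 with q = 0.0021 in the authors' deposited table. OSH1, a shoot meristem marker fixed to look for meristem tissue, was in neither list. Outside the lists, Os07g0529000 went from 0 to a mean of 258 reads in the authors' deposited table, at least 157-fold higher against a floor of 3 reads over the control group, with a 95% counting interval from 128-fold. At the other end, Os11g0262600 and Os01g0561500 went from means of 16.5 and 12.5 reads to 0 in the authors' deposited table, at least 12-fold and 9.07-fold lower against the same floor, with 95% counting intervals of the ratio up to 0.108 and 0.146.

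**Figure D1:**
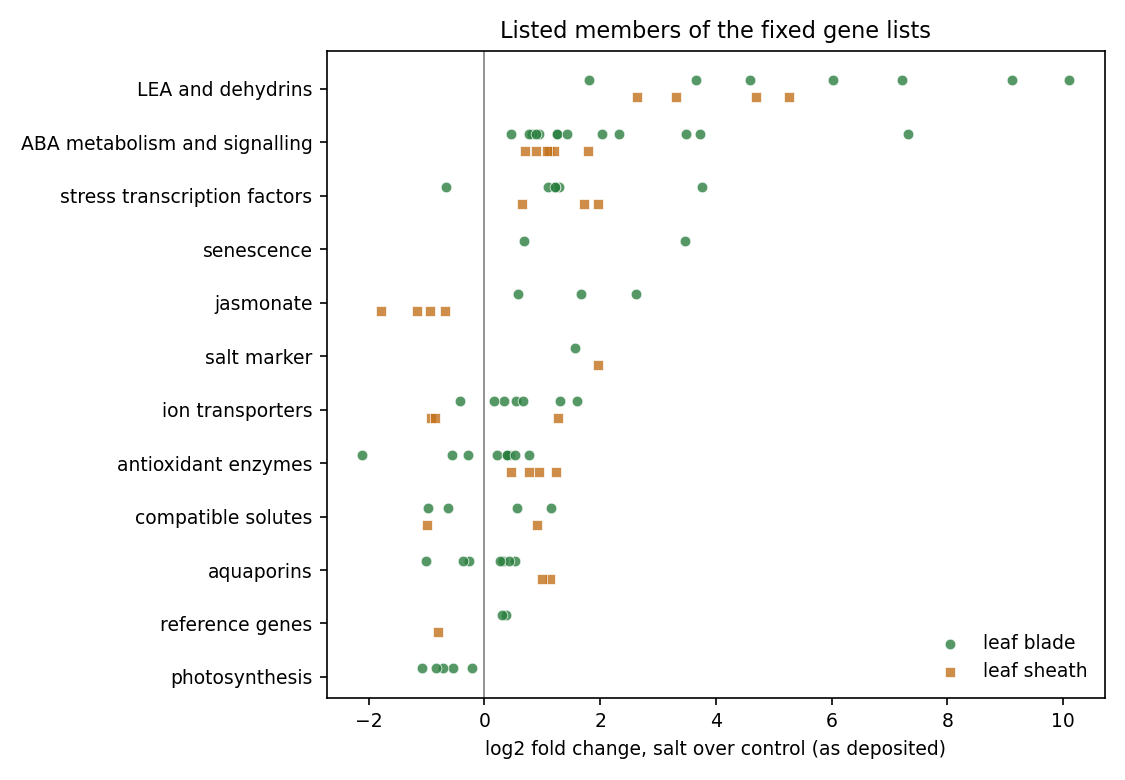
Log2 fold change of salt over control (x axis, as deposited) for each listed member of the fixed gene lists (y axis, 1 line per list), with circles for leaf blades and squares for leaf sheaths. The 7 LEA and dehydrin genes of blades have a median of 6.02 (4.58 with RAB16D, at 0 control reads, set to its floor), the 5 photosynthesis genes of blades lie below 0, and the jasmonate genes lie above 0 in blades and below 0 in sheaths.

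In leaf sheaths with salt, LEA3-1 and RAB21 had the largest rises of the named genes and AOS2, a gene of jasmonate synthesis, the largest fall, while no list passed its test. Lists had at most 6 listed members there, and 6 of 6 higher gave adjusted p = 0.099 (exact binomial test). Lists this short could therefore hardly pass, which is not evidence against a direction. The authors' deposited table for sheaths held 911 genes higher and 1087 lower with salt, so 45.6% were higher. By the authors' deposited table, 416 genes rose and 346 fell by at least 1 on the log2 scale, and 87 rose and 4 fell by at least 2. Without the 8 genes listed at 0 in a group, 412 rose and 344 fell by at least 1, and 84 rose by at least 2. The standard errors in the authors' deposited table had a median of 0.197 and ran from 0.128 to 1.73. They belong to statistic times standard error and not to the listed fold change, which was the smaller of the 2 in size for named genes at low levels. Both values are given below for each gene whose standard error is printed.

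All 4 listed LEA and dehydrin genes of 10 were higher in sheaths in the authors' deposited table (exact binomial test, p = 0.043, adjusted p = 0.16), with a median log2 fold change of 4.01. LEA3-1 went from a level of 0.078 to 40.3, a listed log2 fold change of 5.26, while statistic times standard error in the authors' deposited table gave 8.71 with a standard error of 0.86. RAB21 rose from 1.51 to 64.2, a log2 fold change of 4.70 with adjusted p = 1.0e-47 in the authors' deposited table. Its statistic times standard error was 5.45, with a standard error of 0.362. RAB16B and RAB16C had listed log2 fold changes of 3.32 and 2.63 in the authors' deposited table. Their statistic times standard error was 4.43 and 3.74, with standard errors of 0.43 and 0.529. All 6 listed members of the 16 abscisic acid genes were higher in the authors' deposited table (exact binomial test, p = 0.0090, adjusted p = 0.099). The largest listed change was that of Os07g0154100, a member without a checked name, at 1.79 on the log2 scale. PP2C08 rose by 1.21 and ABA8ox2, which breaks down abscisic acid, by 1.11 on the log2 scale in the authors' deposited table. PP2C09 rose by 1.08 and PP2C49 by 0.89 in the authors' deposited table. In the same order, statistic times standard error was 1.36, 1.39, 1.14 and 0.998, with standard errors of 0.229, 0.253, 0.157 and 0.199.

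SALT went from a level of 113 to 444 in sheaths, a log2 fold change of 1.96 in the authors' deposited table. Its statistic times standard error was 1.99, with a standard error of 0.495. All 3 listed stress transcription factors of 10 were higher (exact binomial test, adjusted p = 0.30), with HSFA2C at 1.73 and NAC5 at 0.65 on the log2 scale in the authors' deposited table. The remaining member, Os11g0126900, without a checked name, was at 1.96. All 4 listed antioxidant enzymes of 10 were higher (exact binomial test, adjusted p = 0.16), with APX8 at 0.94 and APX2 at 0.46 on the log2 scale in the authors' deposited table. Os03g0131200, a member without a checked name, had the largest listed change of them, 1.23. Both listed aquaporins of 13 were higher (exact binomial test, adjusted p = 0.44), with PIP1;3 at 1.14 and TIP1;2 at 1.0 on the log2 scale in the authors' deposited table.

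All 4 listed jasmonate genes of 10 were lower in sheaths in the authors' deposited table (exact binomial test, adjusted p = 0.32). AOS2 and AOS1, allene oxide synthases of jasmonate synthesis, changed by -1.78 and -0.95 on the log2 scale in the authors' deposited table. Their statistic times standard error was -2.01 and -0.93, with standard errors of 0.259 and 0.167. AOS2 went from a level of 14.9 to 3.63. The repressor gene JAZ9 changed by -1.16 in the authors' deposited table. Its statistic times standard error was also -1.16, with a standard error of 0.196. Of the 18 ion transport genes, 1 was higher and 2 were lower in sheaths in the authors' deposited table (exact binomial test, adjusted p = 1). HKT1;3, a sodium transporter gene, rose by 1.27 from a level of 4.04 to 11.2 with a standard error of 0.255 in the authors' deposited table. The potassium channel gene AKT1 changed by -0.93 and HAK1 by -0.85 on the log2 scale in the authors' deposited table. Their statistic times standard error was -0.98 and -1.21, with standard errors of 0.17 and 0.325. The compatible solute list had 1 member higher and 1 lower (exact binomial test, adjusted p = 1), and TPP1 changed by -0.99 on the log2 scale in the authors' deposited table. The 1 listed reference gene was lower (exact binomial test, adjusted p = 1), and no photosynthesis, senescence or shoot meristem gene was listed in sheaths. Outside the lists, Os11g0211800 had the highest listed log2 fold change of the authors' deposited table, 5.48, from a level of 6.63 to 339. Its statistic times standard error was 5.68, with a standard error of 0.214, below the 8.71 of LEA3-1. The lowest listed values were those of Os10g0334500 at -2.58 and Os02g0306401 at -2.17 on the log2 scale in the authors' deposited table. Their statistic times standard error was -3.52 and -2.41, with standard errors of 0.634 and 0.267.

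Between the tissues, the 2 lists shared 794 genes. Of these, 468 were higher in both tissues, 47 lower in both, 102 higher in sheaths and lower in blades, and 177 lower in sheaths and higher in blades, by the authors' deposited tables. The same direction was therefore seen in 515 genes, or 64.9%, where independent directions at the same margins would give 63.6% (two-sided Fisher's exact test across genes, odds ratio 1.22, p = 0.31; genes are not independent replicates). Of the sheath genes that rose, 62.6% were also in the blade list, against 20.6% of those that fell. Among the shared genes with a log2 fold change of at least 1 in both tissues, 207 were higher in both, 10 lower in both, 7 higher in sheaths alone and 3 higher in blades alone, so that 95.6% had the same direction (Fisher's exact test across genes, odds ratio 98.6, p = 6.2e-11). Since 207 of these 227 were higher in both, independent directions at their margins would also often be the same, at a share not computed. The 95.6% therefore cannot be set directly against the 64.9%. The minimum of 1 was applied to listed values, which are different fold estimates in the 2 tables. HAK1, at 1.61 in blades, missed it in sheaths at a listed -0.85, though statistic times standard error gave -1.21. The counts at this minimum therefore depend on the scale of the sheath values. Lists drawn independently would share 794 genes if 11633 genes had been tested in both tissues. The number tested in blades is not given in the sources used here, and the adjusted p of the sheath table corresponds to about 32000 tests, at which independent lists would share 289 genes.

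LEA3-1, RAB21, RAB16B, RAB16C and SALT were the 5 named genes with the largest changes in the same direction in both tissues, ranked by the smaller change, and all 5 were higher. The opposite directions held 2 named genes in the authors' deposited tables. HAK1 changed by -0.85 in sheaths and 1.61 in blades on the log2 scale, and APX8 by 0.94 in sheaths and -0.56 in blades, in the authors' deposited tables. Neither the genes nor the lists were shown to differ in response between tissues, since a tissue by treatment term could not be fitted without values per sample. The split of higher and lower members differed between tissues at an unadjusted level for jasmonate genes, 3 higher in blades and 4 lower in sheaths, but not over the 10 lists tested (Fisher's exact test, p = 0.029, adjusted p = 0.29). With 3 and 4 listed members no split could be more uneven, so the result does not speak against a difference.

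**Figure D2:**
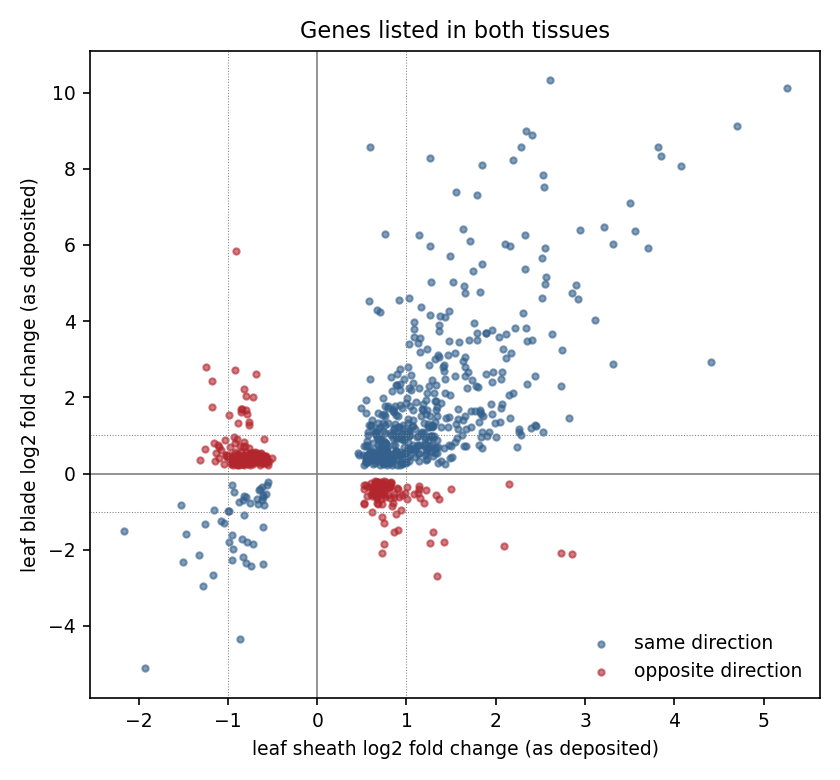
Log2 fold change of salt over control in leaf sheaths (x axis) and leaf blades (y axis), as deposited, for the 794 genes listed in both tissues, 1 point per gene, with blue for the same and red for the opposite direction and dotted lines at a log2 fold change of 1 and -1. Of the 279 genes with opposite directions, 10 lie beyond the dotted lines in both tissues.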

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

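The test of a label swap, the later test of a scaling shift and the tests of list splits between tissues were chosen after the fold changes they use had been seen, as were the medians by direction. Of the 794 genes listed in both tissues, 279 had opposite directions, 177 of them lower in sheaths and higher in blades. In the jasmonate list, 3 of 3 listed members were higher in blades and 4 of 4 lower in sheaths, a difference that did not pass after adjustment over 10 lists (Fisher's exact test, p = 0.0286, adjusted p = 0.29) and was not tested over samples. These were mostly different genes, and 1 was listed in both tissues.

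Of the 224 shared genes that were lower in sheaths, 79.0% (exact 95% interval 73.1% to 84.2%) were higher in blades, as were 82.1% (78.7% to 85.2%) of the 570 that were higher in sheaths, against 45.6% of the 3829 blade genes that were not in the sheath list. A raised share was thus seen in both groups, but the sizes of the blade changes differed. The median blade log2 fold change was 0.40 for genes lower in sheaths and higher in blades, and 1.22 for genes higher in both. A swap of the control and salt labels in one table is argued against by the LEA, dehydrin and abscisic acid genes listed in both tissues, of which 9 of 9, or 100%, had the same direction (exact 95% interval from 66.4%). A scaling shift in the blade table stays open: the test planned before its result gave 42.9% higher in blades among sheath-lower genes with a blade log2 fold change of at least 1 in size (18 of 42), and one added later gave 94.8% of 135 sheath-lower genes against 42.8% of 1159 genes not in the sheath list among changes under 0.5, a difference of 52.0 points. Both select genes by the size of the change whose sign they count, so neither decides. A different expression level of the shared genes was examined in 3 classes of blade TPM. In the middle and highest classes, 78.7% and 88.9% of the sheath-lower genes were higher in blades. Genes not in the sheath list gave 48.7% and 34.4% there, so the excess was 29.9 and 54.5 points. Among those other genes the share fell with level, which argues against level alone as the source in these 2 classes. In the lowest class the excess was 2.18 points (54.3% against 52.2%), so nothing is settled there. A response of these genes that differs between tissues also stays open and was not tested.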

How the results depend on the processing

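No paired analysis was possible because the deposited tables hold no values per sample. For the same reason leaving out a replicate, another normalization, another test and the tissue by treatment term were not run, nor were the keyword lists. Another pseudocount could have been tried on the sheath group levels and was not run. Requiring an absolute log2 fold change of at least 1 left 1495 blade genes (917 higher), 762 sheath genes (416 higher), 227 shared genes and 10 shared genes with opposite directions. It raised the share higher from 51.7% to 61.3% in blades and from 45.6% to 54.6% in sheaths. The same minimum ended the call of the abscisic acid list in blades with 8 members left, by construction with both fewer members and a higher share to test against, whose parts in it were not tested, and turned the balance of 3 lists that had no call. These were antioxidant enzymes in blades (0 higher, 1 lower), aquaporins in blades (0 higher, 1 lower) and ion transporters in sheaths (1 higher, 0 lower). Added after seeing the data, q up to 0.004 in blades left 3060 genes (1584 higher) and 162 shared genes with opposite directions, and a minimum of 1 on statistic times standard error left 912 sheath genes (488 higher). The even splits of compatible solutes became uneven, in blades with the fold minimum (1 higher, 0 lower) and with checked names alone (2 higher, 1 lower) and in sheaths with checked names alone (0 higher, 1 lower). Of 74 list results under other settings, 67 kept their direction and side of the threshold, and lists with no member left gave none. The 56 named values that could be put on another scale (TPM ratio or statistic times standard error) had 0 changes of direction. Low control reads limit the size of the largest blade rises, and the missing spread between samples limits every blade value.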

Other observations

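The medians and shares by direction were chosen after the directions had been seen, and the tests of neighbours and of chromosome ends before their results. The 177 genes lower in sheaths and higher in blades had a median sheath level of 177, against 49.8 for the 102 genes of the other opposite kind, 48.6 for the 47 lower in both and 15.3 for the 468 higher in both. Their median blade control TPM was 41.8, against 123, 23.7 and 12.5 in the same order. A blade log2 fold change under 0.5 in size was found in 72.3% of them, against 50%, 14.9% and 15.8% of the others. Within the 570 shared genes that rose in sheaths, the fold changes of both tissues ranked alike (Spearman's rho 0.59 across genes, which are not independent), while within the 224 that fell in sheaths rho was 0.02.

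Genes with neighbouring locus numbers tended to be listed in the same direction. The dehydrin genes RAB16D, RAB16C, RAB16B and RAB21 of chromosome 11 were all higher in blades. Of 522 blade pairs with locus numbers at most 100 apart, 61.1% shared a direction, against 50.1% when directions were permuted (permutation p = 1e-05, the smallest 100000 permutations can give), and of 123 sheath pairs 71.5% did, against 50.4% (permutation p = 1e-05). Without the blade genes whose mean reads are not means of 2 whole numbers, 59.4% of 478 pairs still shared a direction (permutation p = 2e-05). This argues against reads split in fractions between neighbouring copies as the whole source in blades. Reads assigned whole to a single copy would leave no such mark, so sharing of that kind stays open. For sheaths no read counts are given, and sharing was not tested. Shared control of duplicated neighbours or of a chromosome region may contribute and was not tested.

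Mean blade reads that are not means of 2 whole numbers, found in 258 genes, were more frequent at the starts of chromosomes 11 and 12, although only 55 of the 258 genes lay there. They occurred in 37.7% of the 146 listed genes with low locus numbers there, against 4.53% elsewhere (Fisher's exact test, odds ratio 12.7, p = 3.7e-33). Reads shared between copies that the ends of these chromosomes have in common are a candidate explanation, and fold changes of single genes there may be mixtures of both copies.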
